A study of Homo sapiens with 24 samples.

How the data were processed

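RNA sequencing of 24 libraries from primary human pulmonary microvascular endothelial cells was analysed from a single table of 25506 genes. The values were deposited by the authors as CPM, reads scaled to an equal total over the genes of each library, with a constant of 1e-04 added to every value. The columns summed to between 1000002 and 1000003, which is what CPM plus this constant gives. TopHat2 and Partek are named, without versions or roles, per the submitters' processing notes, and the counting rule, its treatment of strand and the annotation are not given in the sources used here. The same notes name the mouse genome build mm10, whereas the symbols and coordinates in the table were human. Of the symbols, 24392 occurred once in GENCODE release 29, and 24210 of these (99.3%) overlapped the GENCODE gene on GRCh38, so coordinates are given as the table lists them, on GRCh38. All value columns were matched to samples by the sample identifier in their name.

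Each library's depth was estimated from the smallest steps between its low CPM values. It lay between 30312200 and 48005000 reads. In the libraries between 85.5% and 87.0% of low values were whole reads within 0.1 read, the others fell between whole reads, and whole read counts were not recovered. A value of 1 CPM stands for about 30 to 48 reads, and genes at a few CPM carry more counting error than abundant genes. Reads from overlapping genes, read-through names and near-identical copies are uncertain, and so are antisense genes.

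The 8 groups were the 4 treatments (Ctrl, Hb2+, Hb3+ and Hemin) at 30 min and at 1.5 h, with 3 libraries each. The replicate numbers 1 to 3 stand for 3 primary cell donors, per the series' design text and the sample titles. Deviations from the group means were compared over the 84 pairs of libraries with the same number. Their lowest correlation was 0.884 and their median 0.943, the highest correlation between different numbers was -0.13, and 24 of 24 libraries correlated best with a library of their own number. Subtracting the group means pushes correlations between different numbers below 0 by construction, so the check rests on the pairs with the same number. The donor block had been fixed beforehand from the design text, and it was kept. No columns were identical, and the highest correlation of 2 libraries was 0.998.

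Genes with a mean of at least 1 CPM over all libraries were tested (14968 genes). The values were transformed to log2(CPM + 1), since the authors deposited CPM and not counts. Fold changes are on this log2(CPM + 1) scale, which understates the change of genes at a few CPM. A linear model with group and donor was fitted to all 24 libraries with limma (lmFit and eBayes with a trend), with 14 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. A gene was called at an adjusted p under 0.05. Tests are two-sided. With 3 donors an exact sign-flip test of a single gene cannot give a p below 0.25, so single genes rest on the model. The comparisons were each treatment against Ctrl at each time, Hb3+ against Hb2+ and Hemin against Hb3+ at each time, Ctrl at 1.5 h against 30 min, and for each treatment the difference between its effects at the 2 times.

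Before the data were examined, 26 gene lists (522 genes, 497 in the table and 468 tested) were fixed, and so was the rule for the genes that are named. The lists were tested with camera in limma with its preset correlation between genes, for lists with at least 3 tested members, and adjusted over the lists by the Benjamini-Hochberg method. The estimated correlation and fry served as alternatives. The erythroid list could not be tested, since 5 of its 16 genes were in the table and 1 passed the filter. The rule named, for each treatment against Ctrl, up to 12 called genes with the highest and up to 12 with the lowest fold change among those with the same sign in all 3 donors. Where fewer than 5 passed it named the 5 genes with the smallest p, as values. For the other comparisons the limit was 6 in each direction, for each list it was the 4 members with the smallest adjusted p, and HMOX1 was named throughout. Genes without a proper name were counted and not named. Genes outside this rule are said to have been chosen after their values were seen.

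The alternatives fixed before the data were examined were no donor block, pseudocounts of 0.25 and 5, no filter, a filter at 10 CPM, median-of-ratios and quantile rescaling, fits of the compared groups alone, and leaving out each donor and each library in turn. A correction for GC content and transcript length (14785 tested genes with both values, 98.8%) and a covariate for epithelial marker RNA were added after seeing the data. The number of called genes was recounted over the other splits of the compared libraries. The same steps were tested on simulated data for Hb3+ against Ctrl at 1.5 h, with 200 of the 14968 genes changed. Calls recovered 53.7% of the genes changed by 0.3 on the log2 scale, 86.6% of those changed by 0.6 and 97% of those changed by 1.2, and 7 of 165 calls were false. Over the 8 simulated comparisons without a change there were 0 false calls by limma, and the 95% intervals held 0 for 95.1% of the unchanged genes. The simulated genes varied independently of each other, whereas genes of the real libraries vary together, so these rates need not hold for the real data. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 were used.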

Results

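Primary pulmonary microvascular endothelial cells, the cells that line the small vessels of the lung, were exposed to haemoglobin or to hemin, the iron porphyrin freed from it. Hb2+ carries ferrous and Hb3+ ferric haem iron, and both were given at 1 mg/mL. Hemin was given at 60 µM, and control cells (Ctrl) received water. RNA was sequenced after 30 min and after 1.5 h, with 3 donors in each of the 8 groups and 24 libraries in all. Estimated depth ran from 30312200 to 48005000 reads per library. Levels are given in CPM as mean ± SD over 3 libraries, fold changes as log2 with the SE from limma.

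The donors differed far more than the treatments. The first principal component held 62.5% and the second 29.2% of the variance, and both separated the replicate numbers. In replicate 3, most tested genes of fibroblasts and mural cells were abundant. The collagen gene COL1A1 stood at 19570 ± 608 CPM (SD, n = 8) there, against 7.95 CPM in replicate 1 and 7.66 CPM in replicate 2. Likewise COL3A1 stood at 4935 CPM in replicate 3, and the mural receptor gene PDGFRB at 117 CPM. Of the 17 tested genes of this list, 14 were over 10 times higher in replicate 3, whereas the pericyte gene RGS5 was lower there, at 5.67 CPM against 272 and 1064 CPM in replicates 1 and 2. Endothelial markers other than PLVAP were lower there, with PECAM1 at 821 ± 19.1 CPM against 2767 and 2851 CPM in replicates 1 and 2, whereas PLVAP stood at 75.4 CPM against 94.0 and 9.83 CPM. The lymphatic regulator gene PROX1 also varied, from 150 CPM in replicate 1 to 5.15 CPM in replicate 2. Genes of airway epithelium were present in every library at an even level. The cytokeratin gene KRT19 averaged 714 CPM (586 to 829 CPM over the 24 libraries) and the club cell gene SCGB1A1 119 CPM (94.3 to 139 CPM). Of the 11 tested epithelial genes, 9 lay within 1.2-fold over the 3 donors. Erythroid transcripts were nearly absent, and the highest value of that list was 43.0 CPM for the mitochondrial iron importer gene SLC25A37, which other cells also express.

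The first question was which genes haemoglobin and hemin changed within 30 min. With Hb2+, ARRDC3, which encodes an alpha-arrestin of receptor trafficking, fell from 101.5 ± 21.9 to 74.6 ± 19.7 CPM (log2 fold change -0.45, SE 0.06, n = 3; limma adjusted p = 0.00985 by Benjamini-Hochberg). With Hb3+ it fell to 66.8 ± 16.7 CPM (log2 fold change -0.60; limma adjusted p = 0.000111 by Benjamini-Hochberg). Hb3+ also lowered ADM, the gene of the vasodilator peptide adrenomedullin, from 89.7 ± 26.9 to 69.9 ± 19.9 CPM (log2 fold change -0.35; limma adjusted p = 0.0015 by Benjamini-Hochberg). ARRDC3 lies at 91368631 to 91383318 on the minus strand of chromosome 5 and ADM at 10305073 to 10307398 on the plus strand of chromosome 11. HMOX1, the gene of haem oxygenase 1 that opens the haem ring, differed from Ctrl by 0.07 with Hb2+, 0.06 with Hb3+ and 0.08 with Hemin on the log2 scale (SE 0.12), within its error. ALAS1, the gene of the first enzyme of haem synthesis, had the smallest p with Hemin, at 42.5 ± 6.07 CPM against 52.4 ± 2.54 CPM (log2 fold change -0.31), and did not pass over all genes (limma adjusted p = 0.159 by Benjamini-Hochberg). With Hemin and with Hb3+ it passed when adjusted over the list alone, as 1 of the 11 haem synthesis genes.

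In total limma called 1 gene with Hb2+, 2 genes with Hb3+ and 0 genes with Hemin at 30 min. At an unadjusted p under 0.05 there were 494, 577 and 872 of the 14968 tested genes. Without any effect a share of 0.05 is expected on average. The counts with Hb2+ and Hb3+ lay below that share and the count with Hemin above it. Among the uncalled genes with the smallest p were the cobalamin gene MMADHC (log2 0.12 with Hb2+ and 0.15 with Hemin), the respiratory chain gene UQCRQ and the ribosomal gene RPL7A (0.16 and 0.26 with Hb2+), IRF2BP2, ZNF594 and MEX3B (-0.18, -0.38 and 0.21 with Hb3+), and SELENOT and BPNT1 (0.19 and 0.22 with Hemin). BOLA2 stood at -1.74 with Hemin, but it shares nearly its whole sequence with BOLA2B and its value is uncertain. No gene was called in the 3 comparisons without the donor block (0 genes in each). ARRDC3 with Hb2+ was also not called in the fit of the compared groups alone (0 genes) or without replicate 1, replicate 3, Ctrl replicate 1, Ctrl replicate 3, Hb2+ replicate 2 or Hb2+ replicate 3 (0 genes each), whereas the compared groups alone gave 18 genes for Hb3+ and 2 genes for Hemin. Without replicate 1 or 3 there were 0 genes for Hb3+, without replicate 2 there was 1, and without replicate 3 there was 1 for Hemin.

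Several gene lists stood apart at 30 min by camera with its preset correlation, and all of these calls were lost with an estimated correlation. With Hemin the 28 interferon-stimulated genes were all above Ctrl, with a median log2 fold change of 0.15 (adjusted p = 1.95e-07 by limma's camera with Benjamini-Hochberg, and adjusted p = 0.834 with an estimated correlation). IRF9, USP18, DDX58 and IFIH1, genes of interferon signalling and viral RNA sensing, stood at 0.17, 0.19, 0.16 and 0.18. No interferon gene was called, and 0 passed adjusted over the list alone. The epithelial markers moved beside them, with a median of 0.10 and 10 of 11 above Ctrl (adjusted p = 0.290). By donor, the interferon median was 0.31, 0.14 and -0.02 in replicates 1, 2 and 3, and the epithelial median 0.28, 0.06 and -0.03. Also with Hemin, 24 of 27 heat shock genes were above Ctrl (median 0.06, adjusted p = 0.000624; adjusted p = 0.473 with an estimated correlation), 18 of 28 junction genes were below (median -0.02, adjusted p = 0.0316; adjusted p = 0.254 with an estimated correlation), and so were 14 of 18 endothelial markers (median -0.04, adjusted p = 0.0446; adjusted p = 0.834 with an estimated correlation). None of these 3 lists had a called member, and 0 passed adjusted over the list alone. The 4 Hemin lists were not called without the donor block (smallest adjusted p = 0.0909) or without replicate 1 (smallest adjusted p = 0.132), and the junction list also not without replicate 2 (adjusted p = 0.131). With the epithelial covariate the endothelial list had adjusted p = 0.565.

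With Hb3+ at 30 min the immediate early genes, transcription factors and phosphatases of the first response to growth signals, were lower as a set. Of the 29 tested, 22 were below Ctrl (median -0.09, adjusted p = 0.000164 by limma's camera with Benjamini-Hochberg; adjusted p = 0.5999 with an estimated correlation). No member was called over all genes and JUN (log2 -0.20) passed adjusted over the list alone, while the phosphatase gene DUSP1 stood at -0.39. In the same comparison 25 of 33 genes of haem breakdown, iron storage and antioxidant defence were above Ctrl (median 0.04, adjusted p = 0.0327; adjusted p = 0.5999 with an estimated correlation), as were 25 of 28 cell cycle genes (median 0.04, adjusted p = 0.00319; adjusted p = 0.5999 with an estimated correlation), with 0 members called and 0 adjusted over the list alone. The leukocyte markers (6 of 6 above, median 0.07) and the epithelial markers (8 of 11 above, median 0.03) moved the same way and were not called. With Hb2+ the 13 mitochondrially encoded transcripts were all below Ctrl (median -0.10, adjusted p = 0.0117; adjusted p = 0.905 with an estimated correlation) and 21 of 28 cell cycle genes above it (median 0.04, adjusted p = 0.0188; adjusted p = 0.905 with an estimated correlation), again with 0 members called and 0 adjusted over the list alone. Without the donor block the cell cycle lists had adjusted p = 0.289 with Hb2+ and 0.333 with Hb3+, and the haem and antioxidant list 0.899. Without replicate 3 the mitochondrial list turned from lower to higher by camera, with adjusted p = 0.711. The cell cycle lists then had adjusted p = 0.0561 with Hb2+ and 0.0873 with Hb3+. The Hb2+ cell cycle list had 0.244 without replicate 2 and 0.297 with the epithelial covariate, where 10 of 11 epithelial markers were below Ctrl, and the haem and antioxidant list had 0.360 and 0.191 without replicates 1 and 2.

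After 1.5 h Hb2+ had lowered a small group of genes. SLC30A1, the gene of the zinc exporter ZnT1, fell to 90.5 ± 7.22 CPM against 121.9 ± 2.37 CPM (log2 fold change -0.43, SE 0.04, n = 3; limma adjusted p = 1.11e-05 by Benjamini-Hochberg). ARRDC3 remained lower at 68.0 ± 17.7 CPM against 102.7 ± 29.1 CPM (log2 fold change -0.58; limma adjusted p = 0.000106 by Benjamini-Hochberg). NEAT1, the RNA that builds nuclear paraspeckles, fell by 0.73 on the log2 scale, the chromatin protein gene HMGB2 by 0.32, the linker histone gene H1FX by 0.28, MDM2, whose product degrades p53, by 0.29, SPAAR by 0.38 and the amino acid transporter gene SLC43A2 by 0.21. RBM15B, which encodes an RNA-binding protein, rose by 0.19. HMOX1 stood at 129.5 ± 41.0 CPM against 127.2 ± 39.8 CPM (log2 0.03, 95% interval -0.22 to 0.27), and ALAS1 at 44.9 ± 3.72 against 50.7 ± 2.13 CPM (log2 -0.17; limma adjusted p = 0.318 by Benjamini-Hochberg). Adjusted over their lists alone, ALAS1 and SLC25A38 passed among the 11 haem synthesis genes TXNRD1 and MAFG among the 33 haem breakdown and antioxidant genes, SLC39A14, SLC39A8 and IREB2 among the 12 iron uptake genes, MDM2 and BBC3 among the 18 p53 targets and ERG among the 18 endothelial markers.

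These were the 9 genes that limma called with Hb2+ at 1.5 h, 1 higher and 8 lower. The metal response list was lower (3 tested genes, median -0.26, adjusted p = 0.000353 by limma's camera with Benjamini-Hochberg; adjusted p = 0.0303 with an estimated correlation), with SLC30A1 called over all genes and 1 gene adjusted over the list alone. The metallothionein genes MT1E and MT2A stood at -0.26 and -0.09. SLC30A1 itself rose with time in Ctrl by 0.25 on the log2 scale (limma adjusted p = 0.00191 by Benjamini-Hochberg). No gene was called without the donor block (0 genes), and without replicate 1 or 2 there were 0 and 2. Leaving out Ctrl replicate 1 or Hb2+ replicate 1 left 5 genes, and leaving out Ctrl replicate 2 or Hb2+ replicate 3 left 3.

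With Hb3+ at 1.5 h the haem oxygenase gene HMOX1 rose and the haem synthesis gene ALAS1 fell, beside many smaller changes. HMOX1 rose 2.67-fold, from 127.2 ± 39.8 to 330.3 ± 31.4 CPM (log2 fold change 1.41, SE 0.12, n = 3; limma adjusted p = 5.02e-07 by Benjamini-Hochberg). ALAS1 fell from 50.7 ± 2.13 to 25.8 ± 2.12 CPM (log2 fold change -0.95, SE 0.05; limma adjusted p = 1.83e-09 by Benjamini-Hochberg). TIPARP, which encodes an ADP-ribosyltransferase induced by the aryl hydrocarbon receptor, rose 2.22-fold, from 49.0 ± 7.41 to 112.5 ± 32.1 CPM (log2 fold change 1.15, SE 0.07; limma adjusted p = 1.09e-08 by Benjamini-Hochberg). HMOX1 lies at 35380361 to 35394208 on the plus strand of chromosome 22, ALAS1 at 52198086 to 52214328 on the plus strand of chromosome 3 and TIPARP at 156673235 to 156706771 on the plus strand of chromosome 3.

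**Figure D1:**
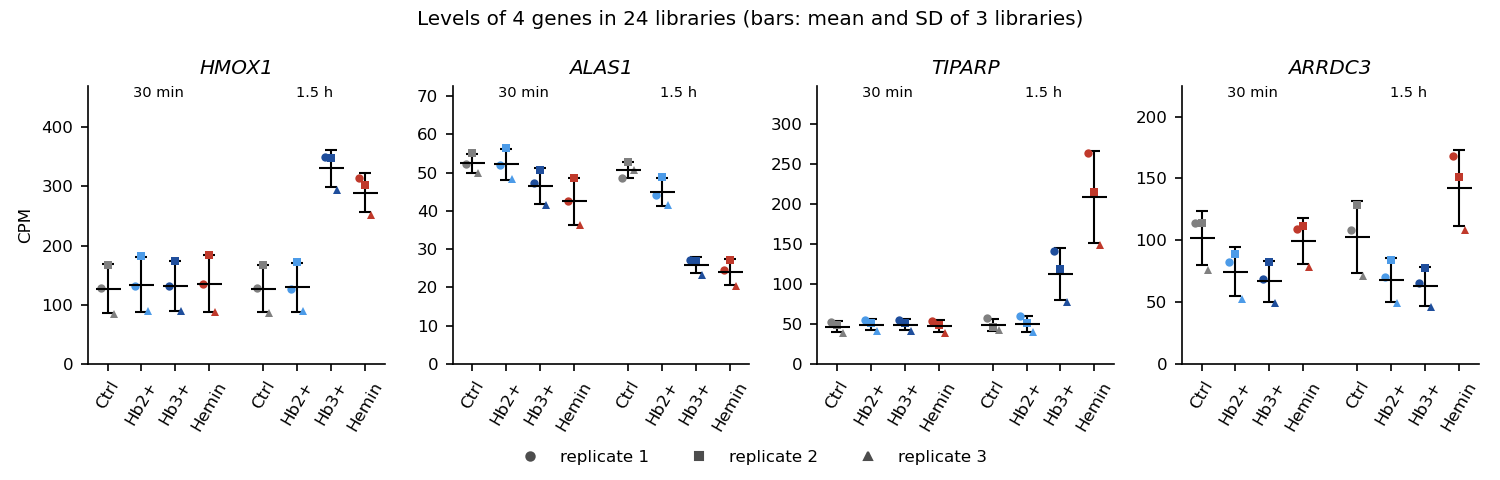
CPM (vertical axis) of HMOX1, ALAS1, TIPARP and ARRDC3 in each of the 24 libraries by treatment and time, with a symbol for each replicate and bars for the mean and SD of 3 libraries. At 1.5 h HMOX1 reaches 330.3 CPM with Hb3+ and 289.3 CPM with Hemin against 127.2 CPM in Ctrl, and ARRDC3 lies below Ctrl with both haemoglobins and above it with Hemin.

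Among the other genes that rose with Hb3+ were PTGS2, the gene of cyclooxygenase 2 (log2 0.85), the stress-responsive IER3 (0.61), the decoy death receptor gene TNFRSF10D (0.45), the cell cycle repressor gene E2F7 (0.39), TNFAIP8L3 (0.36), the splicing kinase gene CLK1 (0.32), the endotoxin receptor gene TLR4 (0.32), DDHD1 and PHF13 (0.30 each). The fallers included ARRDC3 (-0.69), the Notch-modifying gene LFNG (-0.64), NEAT1 (-0.62), SLC30A1 (-0.54), SPAAR (-0.50) and the growth factor gene PDGFB (-0.47). They also included C20orf204, ZNF441, TIGD2, HRCT1 and USP51, which lay at a few CPM (-0.56, -0.52, -0.51, -0.50 and -0.47). ZNF441 itself rose with time in Ctrl, so its value is a level below a risen control and need not be a fall over time. With a pseudocount of 5, C20orf204 stood at -0.28, TIGD2 at -0.31, HRCT1 at -0.23 and USP51 at -0.21. In all limma called 146 genes, 79 higher and 67 lower, with a median absolute log2 fold change of 0.26 and 2 above 2-fold.

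Of the 33 genes of haem breakdown, iron storage and antioxidant defence, 4 rose with Hb3+ at 1.5 h and 0 fell. These were HMOX1, MAFG, the partner of the antioxidant regulator NRF2 (0.31), GCLM of glutathione synthesis (0.25) and the thioredoxin reductase gene TXNRD1 (0.21). Adjusted over the list alone there were 5, with SLC7A11 added. The set as a whole did not pass (median 0.02, adjusted p = 0.0684 by limma's camera with Benjamini-Hochberg). Of the 11 haem synthesis genes ALAS1 alone was called, and the next smallest p belonged to SLC25A38 (0.10). The metal response list was lower (median -0.20, adjusted p = 0.00366; adjusted p = 0.0825 with an estimated correlation and 0.0641 without a filter), with SLC30A1 called and 1 gene adjusted over the list alone. Adjusted over their lists alone, 4 junction genes, 2 iron uptake genes and 2 immediate early genes passed as well, and at most 1 gene of any further list. MDM2 fell by 0.33, and the endothelial genes PTPRB and ERG rose by 0.25 and 0.15. The epithelial markers had a median of -0.07 in this comparison, with 9 of 11 below Ctrl. The count of 146 rested on the donor block (2 genes without it, ALAS1 and SLC30A1) and on the shared spread of all groups (5 genes in the fit of the compared groups alone), and the epithelial covariate gave 237. Without replicate 1, 2 or 3 it was 7, 21 and 59, without Ctrl replicate 2 it was 52, and without Hb3+ replicate 2 or 3 it was 84 and 77.

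Hemin at 1.5 h raised HMOX1 2.33-fold, to 289.3 ± 33.4 CPM (log2 fold change 1.22, SE 0.12, n = 3; limma adjusted p = 5.11e-06 by Benjamini-Hochberg), and lowered ALAS1 2.08-fold, to 24.01 ± 3.40 CPM (log2 fold change -1.06; limma adjusted p = 1.26e-10 by Benjamini-Hochberg). TIPARP rose 4.12-fold, to 209.0 ± 57.3 CPM (log2 fold change 2.04, SE 0.07; limma adjusted p = 3.8e-13 by Benjamini-Hochberg). The cytochrome P450 genes CYP1A1 and CYP1B1, which oxidise aromatic compounds, rose by 1.58 and 1.13. CYP1A1 went from 13.6 ± 3.52 to 49.2 ± 34.1 CPM (SE 0.20; limma adjusted p = 0.000145 by Benjamini-Hochberg), with log2 values of 2.53, 1.18 and 1.04 in replicates 1, 2 and 3. ARRDC3, which fell with both haemoglobins, rose with Hemin to 142.6 ± 30.9 CPM (log2 fold change 0.49; limma adjusted p = 0.000157 by Benjamini-Hochberg).

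Other genes raised by Hemin were the transcription factor gene FOSB (log2 1.40), the vascular early response gene APOLD1 (1.34), PTGS2 (1.09), the cell death gene BMF (0.89), the chemokine gene CCL2 (0.87), IRF2BPL (0.87) and the endothelial transcription factor gene SOX17 (0.83). Lower were the cyclic AMP phosphodiesterase gene PDE4B (-1.20), the endothelial transcription factor genes HHEX (-0.89) and SOX18 (-0.71), the kinase gene PIM3 (-0.72), MYC (-0.68), the metabolic kinase gene PDK4 (-0.65) and the Notch ligand gene DLL4 (-0.61). SPRY1, DUSP6 and SPRY4 were lower too, at -0.74, -0.59 and -0.42. SPRY1 stood at -0.86, -1.29 and -0.06 in replicates 1, 2 and 3. Without replicate 1 HHEX stood at -0.58 (-0.59 without Hemin replicate 1), without replicate 2 SPRY1 at -0.46, and without replicate 3 PPT2-EGFL8 at -0.44. PPT2-EGFL8 stood at -0.69, but its name joins adjacent genes and its reads are uncertain. FOSB, CYP1B1 and PPT2-EGFL8 were at a few CPM, and with a pseudocount of 5 they stood at 0.60, 0.70 and -0.31. In all limma called 73 genes, 41 higher and 32 lower, with a median absolute log2 fold change of 0.56 and 10 above 2-fold.

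The list of NF-kB targets, which holds cytokines, adhesion molecules and feedback inhibitors, rose with Hemin at 1.5 h. Of 31 tested, 27 were above Ctrl (median 0.11, adjusted p = 1.16e-12 by limma's camera with Benjamini-Hochberg; adjusted p = 0.0345 with an estimated correlation). Called over all genes were 2, PTGS2 and CCL2, and adjusted over the list alone 6, with NFKBIA, CSF3, IL1A and IRF1 added. The haem breakdown and antioxidant list rose (33 genes, 21 above Ctrl, median 0.01, adjusted p = 0.000151; adjusted p = 0.0323 with an estimated correlation), with HMOX1 called and 5 adjusted over the list alone (HMOX1, NQO1, GCLM, TXNRD1 and MAFG). The metal response list fell (median -0.25, adjusted p = 4.66e-07; adjusted p = 0.00387 with an estimated correlation), with SLC30A1 called at -0.45 and 2 genes adjusted over the list alone. The fibroblast and mural markers were higher as a set (14 of 17 above Ctrl, median 0.07, adjusted p = 0.000363; adjusted p = 0.0323 with an estimated correlation), with 0 members called and 0 adjusted over the list alone. COL1A1 and PDGFRA stood at 0.35 and 0.30. In replicates 1 and 2 COL1A1 averaged 7.95 and 7.66 CPM, and PDGFRA lay lower still. In replicate 3 COL1A1 varied little over the libraries (19570 ± 608 CPM), so its 0.35 rests mainly on replicates 1 and 2. Genes at such low levels carry more counting error. That set was not called without the donor block (adjusted p = 0.571) or without replicate 3 (adjusted p = 0.157).

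Other lists passed with Hemin at 1.5 h with the preset correlation but not with an estimated correlation. The integrated stress response list was higher (20 of 27 above Ctrl, median 0.03, adjusted p = 0.000354 by limma's camera with Benjamini-Hochberg; adjusted p = 0.277 with an estimated correlation), with 2 genes called and 2 adjusted over the list alone. These were PPP1R15A, which restarts translation after stress (0.62), and the secreted hormone gene STC2 (0.58). The 21 cholesterol synthesis genes had 14 above Ctrl (median 0.03, adjusted p = 0.0116; adjusted p = 0.453 with an estimated correlation), with 0 called and 0 adjusted over the list alone. The TGF-beta and BMP targets were lower (8 of 15 below Ctrl, median -0.0033, mean -0.08, adjusted p = 0.0376; adjusted p = 0.193 with an estimated correlation). Their differentiation inhibitor genes ID3 and ID1 fell by 0.60 and 0.56 and SKIL by 0.24, the 3 genes called, and 5 passed adjusted over the list alone. The haem synthesis list was lower (7 of 11 below Ctrl, median -0.02, adjusted p = 0.0288; adjusted p = 0.198 with an estimated correlation) through ALAS1, the 1 gene called and the 1 adjusted over the list alone. Immediate early genes went both ways, with IER3 (0.76) and FOSB higher and MYC, DUSP6 and SPRY4 lower, 7 genes adjusted over the list alone, and no call of the list (adjusted p = 0.217). Among the other lists without a call, 5 p53 targets, 4 YAP and SRF targets and 3 shear-responsive genes passed adjusted over the list alone, and at most 1 of any further list. Without the donor block limma called 4 genes and the cholesterol and TGF-beta lists were not called (adjusted p = 0.257 and 0.248); the fit of the compared groups alone called 20 genes. Without replicate 1 there were 24 genes, and the stress response, cholesterol and TGF-beta lists had adjusted p = 0.095, 0.307 and 0.723. The cholesterol list had 0.0764 without replicate 2, and the haem synthesis list had 0.073, 0.0764 and 0.0835 without replicates 1, 2 and 3. Without Hemin replicate 1 there were 45, and without Hemin replicate 3 there were 163.

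**Figure D2:**
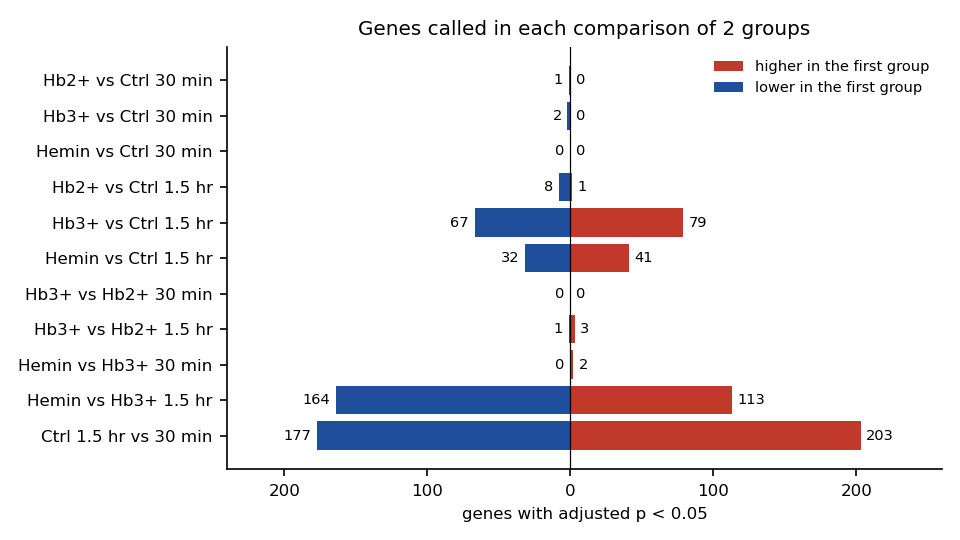
Genes with an adjusted p under 0.05 (horizontal axis, number of genes) in each comparison of 2 groups, with bars to the right for genes higher and to the left for genes lower in the first group. The largest counts are 203 higher and 177 lower for Ctrl with time, 113 and 164 for Hemin against Hb3+ at 1.5 h, and 79 and 67 for Hb3+ against Ctrl at 1.5 h.

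Hb3+ was then compared with Hb2+ directly, which asks what the oxidation state of the haem iron changed. At 1.5 h HMOX1 was 2.62-fold higher with Hb3+ than with Hb2+ (log2 difference 1.39, SE 0.12, n = 3; limma adjusted p = 9.27e-07 by Benjamini-Hochberg) and TIPARP 2.17-fold higher (1.12, SE 0.07; limma adjusted p = 3.84e-08 by Benjamini-Hochberg). ALAS1 was lower by -0.78, at 25.8 ± 2.12 against 44.9 ± 3.72 CPM (limma adjusted p = 3.99e-08 by Benjamini-Hochberg). RAMAC, whose product activates the mRNA cap methyltransferase, was higher by 0.51, and by 0.29 with a pseudocount of 5. PTGS2 was 0.64 higher and did not pass (limma adjusted p = 0.0526 by Benjamini-Hochberg). These 3 higher genes and 1 lower gene were the whole set called at 1.5 h, and 0 gene lists were called. At an unadjusted p under 0.05 there were 632 genes, below the share of 0.05 expected without an effect. Of the haem breakdown and antioxidant genes, HMOX1 passed over all genes, and HMOX1 and GCLM passed adjusted over the list alone.

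At 30 min limma called 0 genes between Hb3+ and Hb2+. The 482 genes at an unadjusted p under 0.05 lay below the share of 0.05 expected without an effect. HMOX1 differed by -0.01 (95% interval -0.26 to 0.23). The smallest p values belonged to the phosphatase gene PTP4A1 (-0.22), C2CD4A (0.50), TSHZ3 (0.41), TMEM38B (-0.32) and the angiogenin gene ANG (-0.31). The immediate early list was lower (20 of 29 below, median -0.06), and the mitochondrially encoded list (13 of 13 above, median 0.08) and the leukocyte list (6 of 6 above, median 0.12) were higher with Hb3+, each with adjusted p = 0.0461 by limma's camera with Benjamini-Hochberg and adjusted p = 0.767 with an estimated correlation, with 0 members called and 0 adjusted over the list alone. Without a filter these 3 lists had adjusted p = 0.100, 0.100 and 0.396, and without replicate 1 they had 0.0696, 0.109 and 0.0696. With the epithelial covariate the leukocyte list had 0.227 and the mitochondrial list 0.0507, and 8 of 11 epithelial markers were higher with Hb3+ (median 0.09). The mitochondrial list had 0.487 without replicate 3, the leukocyte list 0.806 without replicate 2, and the immediate early list 0.114 without the donor block. The 1.5 h count was 1 gene without the donor block, ALAS1, and in the fit of the compared groups alone it was 10.

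Hemin was compared with Hb3+ at matched times. The doses, 60 µM and 1 mg/mL, were given in different units and were not converted to haem. The main haem-responsive genes were not found to differ at 1.5 h. HMOX1 differed by -0.19 (95% interval -0.44 to 0.05; limma adjusted p = 0.543 by Benjamini-Hochberg) and ALAS1 by -0.11 (95% interval -0.22 to 0.01). TIPARP was 0.89 higher with Hemin, CYP1A1 0.92 and CYP1B1 0.83 (limma adjusted p = 1.14e-06, 0.0212 and 0.032 by Benjamini-Hochberg), and these 3 were chosen after their values were seen. CYP1A1 differed by 1.69, 0.60 and 0.48 and CYP1B1 by 0.25, 0.95 and 1.29 in replicates 1, 2 and 3. ARRDC3 differed most, with 142.6 ± 30.9 CPM with Hemin against 62.8 ± 15.9 CPM with Hb3+ (log2 difference 1.18, SE 0.06; limma adjusted p = 6.46e-10 by Benjamini-Hochberg). Also higher with Hemin were the thrombin receptor gene F2RL3 (1.11), the transporter gene SLC16A6 (1.10), IRF2BPL (0.95) and APOLD1 (0.94). SLC16A6 lay at a few CPM, and stood at 0.56 with a pseudocount of 5. Lower with Hemin were HHEX (-0.82), PDE4B (-0.81), SPRY1 (-0.78), DUSP6 (-0.60), MYC (-0.57) and the matrix signalling gene CCN2 (-0.56). Without replicate 2 F2RL3 stood at 0.71, APOLD1 at 0.52 and SPRY1 at -0.50, and without Hemin replicate 2 F2RL3 at 0.63 and APOLD1 at 0.50. Without Hemin replicate 1 HHEX stood at -0.52 and PDE4B at -0.51, and without replicate 1 PDE4B at -0.53.

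In all, 113 genes were higher and 164 lower with Hemin than with Hb3+ at 1.5 h, 276 of the 277 with the same sign in all 3 donors. The excess of lower genes depended on the scaling, with 98 higher and 98 lower after median-of-ratios and 110 and 112 after quantile rescaling. Called members of the lists included the growth arrest gene GADD45A (0.74), the mTOR inhibitor gene DDIT4 (0.61), IRF1 (0.56), the anticoagulant receptor gene THBD (0.56), its regulator KLF2 (0.52), PPP1R15A (0.42), STC2 (0.39), MYLIP (0.34), BBC3 (0.31), NDRG1 (0.22), ID3 (-0.35), PTPRB (-0.27), the gap junction gene GJA1 (-0.27) and ERG (-0.15). Without Hemin replicate 1 GADD45A stood at 0.48 and GJA1 at -0.17, and without Hemin replicate 2 STC2 at 0.25. The NF-kB list was higher (26 of 31, median 0.14, adjusted p = 0.000276 by limma's camera with Benjamini-Hochberg; adjusted p = 0.640 with an estimated correlation), with 2 genes called and 4 adjusted over the list alone. So were the integrated stress response list (22 of 27, median 0.06, adjusted p = 0.00463; adjusted p = 0.640 with an estimated correlation), with 4 called and 6 adjusted over the list alone, and the fibroblast and mural markers (13 of 17, median 0.09, adjusted p = 0.0422; adjusted p = 0.533 with an estimated correlation), with 0 called and 0 adjusted over the list alone. The epithelial markers (9 of 11, median 0.10), the leukocyte markers (6 of 6, median 0.08) and the interferon genes (27 of 28, median 0.06) were also higher and were not called. Of the uncalled lists, 6 p53 targets and 4 immediate early genes passed adjusted over the list alone, and at most 3 of any further list. IRF2BPL was the 1 gene called without the donor block, and the stress response and mural lists had adjusted p = 0.100 and 0.953; the fit of the compared groups alone called 7 genes and the fit without a filter 170. The stress response list had adjusted p = 0.295 without replicate 2, and the mural list 0.126 and 0.122 without replicates 1 and 3. Leaving out replicate 1 or 2 left 14 and 72 genes, leaving out Hemin replicate 1 or Hb3+ replicate 2 left 103 each, Hb3+ replicate 3 left 101, and Hemin replicate 3 gave 446.

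At 30 min ARRDC3 was 0.58 higher with Hemin than with Hb3+ and ADM 0.34 higher (limma adjusted p = 0.000199 and 0.00277 by Benjamini-Hochberg). These 2 were the genes called, both higher, and with median-of-ratios rescaling 66.7% of the calls were higher. HMOX1 differed by 0.02 (SE 0.12). BOLA2B, BOLA2 and KMT2E followed by p, at 0.51, -1.76 and -0.23, and the BOLA2 pair shares reads. The 28 interferon genes were again all higher with Hemin (median 0.14, adjusted p = 6.44e-07 by limma's camera with Benjamini-Hochberg; adjusted p = 0.732 with an estimated correlation), beside epithelial markers with a median of 0.08 and 9 of 11 higher. Immediate early genes were higher (19 of 29, median 0.10, adjusted p = 0.00448; adjusted p = 0.732 with an estimated correlation) and cell cycle genes lower (26 of 28, median -0.05, adjusted p = 0.000515; adjusted p = 0.732 with an estimated correlation). No member of these 3 lists was called, and 0 passed adjusted over the list alone. The cell cycle list had adjusted p = 0.303 without replicate 1 and the immediate early list 0.286 without replicate 2. No gene was called without the donor block (0 genes), without replicate 1 there were 0, without replicate 2 or 3 or Hemin replicate 2 there was 1, and in the fit of the compared groups alone there were 9.

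Genes shared by the treatments were counted at 1.5 h. In total 19 genes were called in the same direction with at least 2 treatments, and SLC30A1 and the small peptide gene SPAAR fell with all 3. All 9 Hb2+ genes were called with Hb3+ as well, against 0.00528 higher and 0.0358 lower genes expected of independent lists. Hb3+ and Hemin shared 12 genes, 7 higher (among them HMOX1, TIPARP, PTGS2, IER3 and E2F7) and 5 lower (ALAS1, SLC30A1, SPAAR, PDGFB and the placental growth factor gene PGF), against 0.216 and 0.143 expected. Hb2+ and Hemin shared 2. These expected numbers leave out the shared Ctrl libraries, and unchanged groups simulated against those libraries shared 0 genes, which the rarity of calls without an effect makes nearly certain, so neither measures an excess. ARRDC3 was called in opposite directions, lower with both haemoglobins and higher with Hemin. All 146 genes called with Hb3+ had the same sign with Hb2+, where the median ratio of fold changes was 0.608, but unchanged groups that share controls gave 95.2% and 0.498, so that part of the excess may come from the shared controls. Over all genes, which are not independent replicates, the covariance of fold changes was 0.00681 for Hb2+ with Hb3+, 0.00359 for Hb2+ with Hemin and 0.00457 for Hb3+ with Hemin, against simulated values of 0.00381, 0.0038 and 0.00378. At 30 min the haemoglobins shared ARRDC3 and no other pair shared a gene. Without the donor block 2 genes were shared at 1.5 h and 0 at 30 min, and without replicate 1 or 2 there were 4 and 9 at 1.5 h, and at 30 min 0 without replicate 1 or 3.

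**Figure D3:**
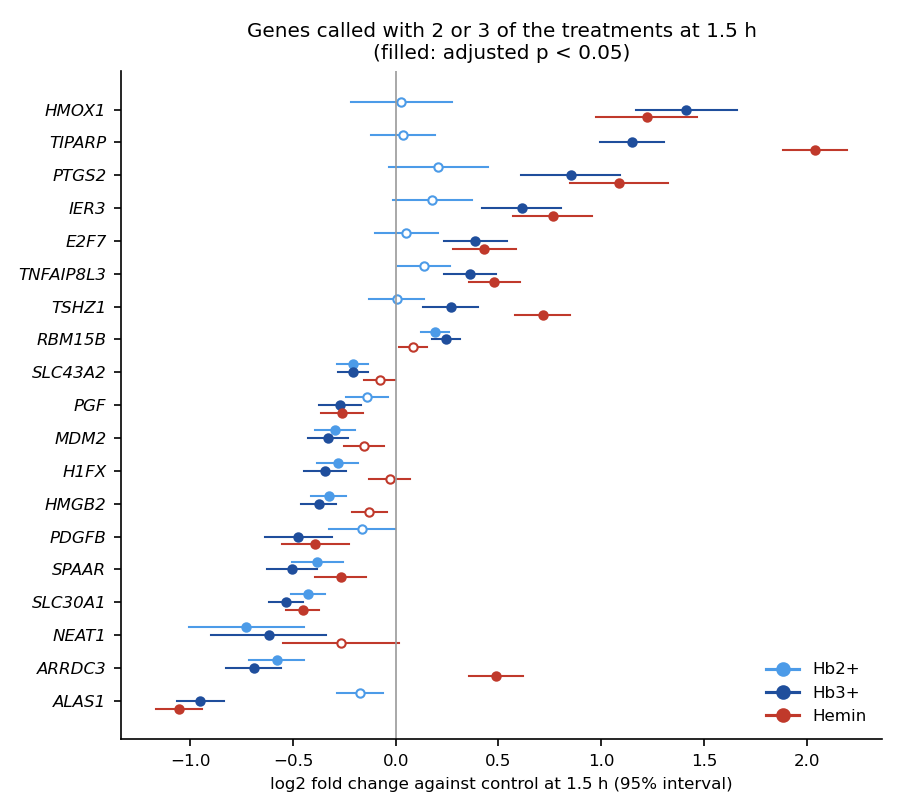
log2 fold change against Ctrl at 1.5 h (horizontal axis, with 95% intervals) of the 19 genes called in the same direction with at least 2 treatments, in a colour for each treatment, with filled points for an adjusted p under 0.05. HMOX1 and TIPARP lie at 1.41 and 1.15 with Hb3+ and near 0 with Hb2+ (0.03 for HMOX1), and ARRDC3 lies on opposite sides of 0 with the haemoglobins and with Hemin.

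Control cells changed between the times as well. The zinc finger gene ZNF441 rose by 0.86 on the log2 scale (SE 0.09, n = 3; limma adjusted p = 2.35e-05 by Benjamini-Hochberg), ANKRD33B by 0.84, ZNF442 by 0.65, MICOS10-NBL1, a name that joins adjacent genes, by 0.62, the growth inhibitor gene BTG2 by 0.60 and the homeobox gene MSX1 by 0.58. EDN1, the gene of the vasoconstrictor endothelin 1, fell from 198.2 ± 85.8 to 134.7 ± 60.7 CPM (log2 fold change -0.56; limma adjusted p = 0.0174 by Benjamini-Hochberg). The kinase gene SGK1 fell by 0.51, THAP2 by 0.50, FLRT2 by 0.46, FAM215B by 0.44 and KLF6 by 0.42. HMOX1 was at 127.2 ± 39.8 and 127.3 ± 41.5 CPM. With a pseudocount of 5, ZNF442, MICOS10-NBL1, MSX1, THAP2 and FAM215B, all at a few CPM, stood at 0.26, 0.39, 0.34, -0.26 and -0.17. Of 380 genes called, 203 were higher and 177 lower (53.4% higher), and with median-of-ratios rescaling 117 were higher and 216 lower (35.1% higher). Without the donor block 1 gene was called, without replicates 1, 2 and 3 there were 12, 24 and 215, and without a filter there were 253. Leaving out Ctrl replicate 1, 2 or 3 of 30 min gave 135, 107 and 240 genes, and leaving out Ctrl replicate 1 or 2 of 1.5 h gave 137 and 132.

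The effect of each treatment at 1.5 h was set against its effect at 30 min. HMOX1 gained 1.36 with Hb3+ and 1.14 with Hemin on the log2 scale (limma adjusted p = 0.000332 and 0.00292 by Benjamini-Hochberg), and differed by -0.04 with Hb2+ (95% interval -0.39 to 0.30). TIPARP gained 1.07 and 2.02, and ALAS1 differed by -0.78 and -0.75. The difference of SLC30A1 was -0.42 with Hb2+, -0.48 with Hb3+ and -0.42 with Hemin. With Hb3+ it was 0.70 for IER3, 0.35 for ADM, 0.34 for RPUSD1, -0.43 for GPCPD1 and -0.35 for MDM2. With Hemin it was 1.63 for CYP1A1, 1.49 for APOLD1, 0.97 for PTGS2, 0.96 for BMF, -1.10 for PDE4B, -0.63 for ID3, -0.58 for MYC and -0.55 for DUSP6. With Hb2+ the next smallest p values belonged to RPL7A (-0.52), HMGB2 (-0.32), SLC43A2 (-0.26) and the respiratory chain gene SDHC (-0.21), which did not pass.

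By limma 1 gene differed between the times with Hb2+, 9 with Hb3+ (5 higher and 4 lower, 55.6% higher, and 45.5% with quantile rescaling) and 30 with Hemin (22 higher and 8 lower, 73.3% higher, and 83.9% with median-of-ratios rescaling). Without the donor block limma called 0 genes in each, with 721, 934 and 862 at an unadjusted p under 0.05 in the blocked fit. The count for Hb2+ lay below the share of 0.05 expected without an effect, and the counts for Hb3+ and Hemin above it. For Hb2+ the count was 2 without replicate 3, Ctrl 30 min replicate 2, Hb2+ 30 min replicate 3 or Hb2+ 1.5 h replicate 2, and 4 without Ctrl 1.5 h replicate 3. For Hb3+ it was 2 and 4 without replicates 1 and 3, and 5 without Ctrl 1.5 h replicate 1, Hb3+ 30 min replicate 3 or Hb3+ 1.5 h replicate 3. For Hemin it was 2 and 17 without replicates 1 and 2. It was 17, 16 and 9 without Ctrl 30 min replicate 1, 2 or 3, 13, 16 and 18 without Ctrl 1.5 h replicate 1, 2 or 3, 11 and 13 without Hemin 30 min replicate 1 or 2, and 77 without Hemin 1.5 h replicate 3.

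Of the 25 tested lists, 9 were called in none of the 10 comparisons between treatments. Their smallest adjusted p values by limma's camera with Benjamini-Hochberg were 0.0593 for the p53 targets, 0.0751 for the YAP and SRF targets, 0.0837 for the lymphatic markers, 0.159 for iron uptake, 0.170 for the epithelial markers, 0.1796 for the hypoxia targets, 0.202 for the unfolded protein response, 0.217 for the shear-responsive genes and 0.314 for the LXR targets.

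The epithelial markers and the interferon-stimulated genes were followed over the libraries, since both varied within donors. Over the 8 libraries of each donor, the mean of the epithelial list and the mean of the interferon list correlated in replicate 1 (Pearson's r = 0.981, exact permutation p = 9.92e-05; Spearman's coefficient 0.976, exact permutation p = 0.000397). The values were r = 0.806 (exact permutation p = 0.00573) and Spearman's coefficient 0.833 (p = 0.0154) in replicate 2, and r = 0.948 (exact permutation p = 0.000124) and Spearman's coefficient 0.976 (p = 0.000397) in replicate 3. Adjusted by Benjamini-Hochberg over the family of 3, the p values of r were 0.000186, 0.00573 and 0.000186. Without the 2 libraries farthest from the median, r was 0.997, 0.733 and 0.853. The highest and lowest libraries did not belong to the same treatment in each donor.

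**Figure D4:**
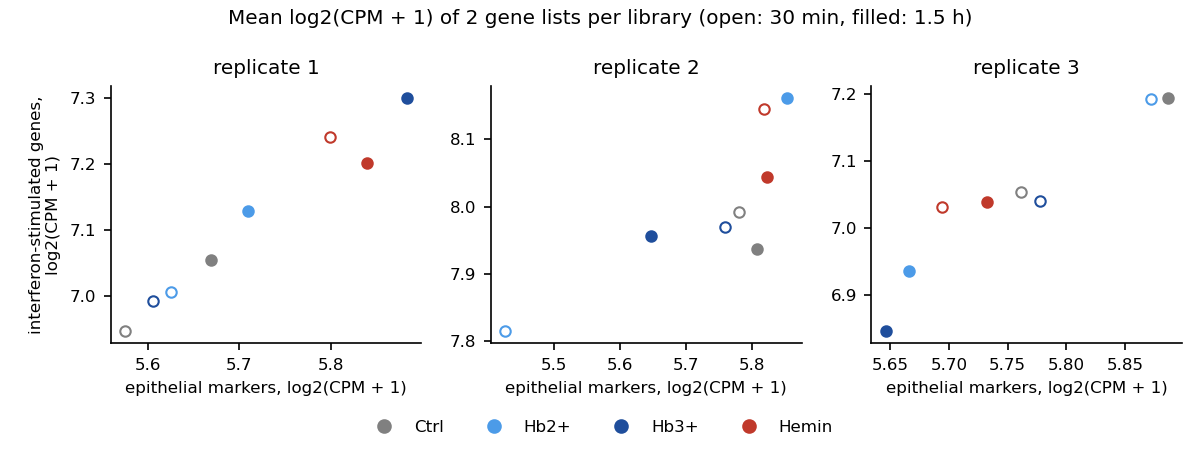
Mean log2(CPM + 1) of the interferon-stimulated genes (vertical axis) against that of the epithelial markers (horizontal axis) in the 8 libraries of each replicate, in a colour for each treatment, open for 30 min and filled for 1.5 h. The libraries rise together in each panel (r = 0.981, 0.806 and 0.948), and the treatments have no common order.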

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

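The tests of GC content and length, of the control libraries and of the epithelial covariate on the Hb3+ genes, and the counts over other splits, were set down before their results were seen; the tests on the interferon list and on replicate 3 were chosen only after the result was seen.

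The effect of each treatment was tested for a difference between 1.5 h and 30 min, and these genes differed between the times by limma. With Hb2+ this was 1 gene, SLC30A1 (-0.42 on the log2 scale). With Hb3+ there were 9 genes, HMOX1 (1.36), TIPARP (1.07), IER3 (0.70), ADM (0.35), RPUSD1 (0.34), ALAS1 (-0.78), SLC30A1 (-0.48), GPCPD1 (-0.43) and MDM2 (-0.35). With Hemin there were 30 genes, and those named were TIPARP (2.02), CYP1A1 (1.63), APOLD1 (1.49), HMOX1 (1.14), PTGS2 (0.97), BMF (0.96), PDE4B (-1.10), ALAS1 (-0.75), ID3 (-0.63), MYC (-0.58), DUSP6 (-0.55) and SLC30A1 (-0.42). Swapping treated and control libraries within donors gave 32 splits for each, and 8 of them called as many genes for Hb2+ (real 1, highest other 6), 5 for Hb3+ (real 9, highest other 78) and 2 for Hemin (real 30, highest other 32). A swap at 1 time in some or all donors leaves part or all of the treatment's own effect in the difference, so these splits are not free of an effect and do not decide about chance. The highest count for Hb2+ and for Hb3+ came from the split that swaps all 3 donors at 1 time, which adds the effects of both times, and without it the highest was 2 for Hb2+ and 29 for Hb3+.

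In the comparisons of 2 groups of 3 libraries, 10 splits exist, which are too few for a share under 0.05. The real count and the highest of the other splits were 1 and 0 for Hb2+ at 30 min, 2 and 0 for Hb3+ at 30 min, and 0 and 0 for Hemin at 30 min, where all 10 splits gave as many. They were 9 and 0, 146 and 0, and 73 and 4 for Hb2+, Hb3+ and Hemin at 1.5 h. For Hb3+ against Hb2+ they were 0 and 0 at 30 min (10 of 10 splits as many) and 4 and 0 at 1.5 h. For Hemin against Hb3+ they were 2 and 1 at 30 min and 277 and 51 at 1.5 h, where the highest among splits that part all 3 pairs of a donor was 1. For Ctrl over time they were 380 and 0. Except where stated, 1 of the 10 splits, the real one, gave as many.

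The 146 genes called with Hb3+ at 1.5 h had mostly small changes and were nearly all lost without the donor block. A trend with GC content or transcript length between libraries was argued against as their whole cause, since 131 of the 146 were still called in the same direction once it was removed. Both values were known for 145 of the 146, and a gene without them was left uncorrected. Control libraries standing apart at 1.5 h were tested with Hb2+ minus Hemin, which uses neither the Ctrl nor the Hb3+ libraries. There 85.6% of the genes had the sign of the call (median 0.11 on the log2 scale in that direction). The genes are not independent, and a library difference common to Hb2+ and Hb3+ would also give such a share, so it does not decide. Epithelial RNA was argued against as well, since 146 of 146 were still called in the same direction with the epithelial covariate. A response of the cells to Hb3+ may be the source, as a hypothesis that these tests leave open. Only 7 and 21 genes were called without replicates 1 and 2, where fewer libraries were also fitted.

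The interferon-stimulated genes were all above Ctrl with Hemin at 30 min, and over the libraries they followed the epithelial markers. RNA or reads of airway epithelial cells in every library could account for this, and the median of the list went from 0.148 to 0.0848 on the log2 scale once the epithelial score was a covariate, which lies within its error of 0.5 times the first value. A response of the endothelial cells could also be the source, but the mean with the covariate (0.08, 95% interval -0.02 to 0.18) lay 1.76 standard errors from 0 (1.30 without the covariate), below the 2 that had been required. The 2 explanations cannot be told apart at a standard error of 0.0456 for the mean left by the covariate. That error comes from the residuals of the model over all 24 libraries.

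Most fibroblast and mural markers, though not RGS5, were high in all libraries of replicate 3, with COL1A1 at 19570 CPM. A mixture with such cells would make them fall where endothelial markers rise, and over the 8 libraries the means of both lists correlated with r = 0.530 (exact permutation p = 0.178; Spearman's coefficient 0.881, exact permutation p = 0.00724; r = 0.66 without the 2 farthest libraries). A mixture made before plating could be equal in every library, so this cannot be told apart from a change of the endothelial cells themselves. No biological explanation was tested, since the labels give the donors no further groups.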

How the results depend on the processing

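The epithelial covariate and the correction for GC content and length were chosen after seeing the data, and the other settings were fixed before the data were examined. edgeR's quasi-likelihood test on whole reads had been planned and was not run, since whole reads were not recovered. Pseudocounts of 0.25 and 5 and the filter at 10 CPM moved no count of genes by over 1.5 times.

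Leaving the replicate block out lowered most counts, because the donors' levels then enter the spread. Without it limma called 0 genes for Hb2+ and 0 for Hb3+ at 30 min, 0 for Hb2+, 2 for Hb3+ and 4 for Hemin at 1.5 h, 1 for Hb3+ against Hb2+ at 1.5 h, 0 and 1 for Hemin against Hb3+ at 30 min and 1.5 h, 1 for Ctrl over time, and 0 for each of the 3 differences between times. It called 1, 1 and 0 lists for Hb2+, Hb3+ and Hemin at 30 min, 5 for Hemin at 1.5 h and 1 for Hemin against Hb3+ at 1.5 h, and 0 genes were shared by treatments at 30 min and 2 at 1.5 h. It moved no other count of genes or lists by over 1.5 times.

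In fits of the compared groups alone, which have fewer libraries for the spread, the counts were 0, 18 and 2 for Hb2+, Hb3+ and Hemin at 30 min, 5 and 20 for Hb3+ and Hemin at 1.5 h, 10 for Hb3+ against Hb2+ at 1.5 h, 9 and 7 for Hemin against Hb3+, and 0 and 19 for the differences of Hb2+ and Hemin between times. Without a filter, which tests more genes, they were 170 for Hemin against Hb3+ at 1.5 h, 253 for Ctrl over time and 19 for the difference of Hemin between times, and 2, 0 and 0 lists were called for Hb2+ at 1.5 h, Hb3+ at 1.5 h and Hb3+ against Hb2+ at 30 min. With median-of-ratios rescaling 1 gene was called for Hemin at 30 min and 0 for the difference of Hb2+ between times, and with quantile normalization 3 for the latter. The GC and length correction gave 1 and 2 for these. The epithelial covariate gave 3 genes for Hemin at 30 min, 237 for Hb3+ at 1.5 h, 4 for Hemin against Hb3+ at 30 min, and 4 and 15 for the differences of Hb2+ and Hb3+ between times, with 4 and 3 lists for Hb2+ and Hb3+ at 1.5 h. Beyond the numbers of libraries and genes, the cause was not tested.

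With an estimated correlation camera called 0 lists for Hb2+, Hb3+ and Hemin at 30 min, 0 for Hb3+ and 4 for Hemin at 1.5 h, 0 for Hb3+ against Hb2+ at 30 min, and 0 and 0 for Hemin against Hb3+ at both times. With fry, which asks whether a list moves and not whether it differs from other genes, 0, 0 and 0 lists were called for Hb2+, Hb3+ and Hemin at 30 min, 2 and 3 for Hb2+ and Hb3+ at 1.5 h, 0 for Hb3+ against Hb2+ at 30 min, and 0 and 0 for Hemin against Hb3+ at both times.

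Leaving out single donors or libraries gave 0 to 1 genes for Hb2+, 0 to 2 for Hb3+ and 0 to 1 for Hemin at 30 min, 0 to 8, 7 to 150 and 24 to 163 at 1.5 h, 0 to 0 and 3 to 4 for Hb3+ against Hb2+, 0 to 3 and 14 to 446 for Hemin against Hb3+, 12 to 378 for Ctrl over time, and 0 to 4, 2 to 11 and 2 to 77 for the differences between times. Lists called ran from 1 to 3, 2 to 3 and 0 to 10 at 30 min and 2 to 4, 1 to 6 and 5 to 9 at 1.5 h for Hb2+, Hb3+ and Hemin, 1 to 5 and 0 to 4 for Hb3+ against Hb2+, and 2 to 6 and 3 to 6 for Hemin against Hb3+. Shared genes ran from 0 to 1 at 30 min and 4 to 19 at 1.5 h.

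Of the 144 called values of named genes, none changed sign under any setting run. Calls were lost for 136 without the replicate block, 82 in the compared groups alone, 25 without a filter, 12 with median-of-ratios rescaling, 6 with the GC and length correction, 5 with quantile normalization, 3 and 2 with pseudocounts of 0.25 and 5, and 0 with the epithelial covariate. They were lost in 230 of 432 runs that left out a donor and 280 of 996 that left out a library. Of the values, 33 were called in every run that left out a donor or a library, among them HMOX1, ALAS1, TIPARP, ARRDC3 and SLC30A1 with Hb3+ and HMOX1, ALAS1, TIPARP, CYP1A1, PTGS2, MYC and DUSP6 with Hemin at 1.5 h. A depth of at least 30312200 reads leaves genes at a few CPM with most of the counting error, and their fold changes moved most with the pseudocount.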

Other observations

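The tests on ERK target and feedback genes and on MondoA targets were chosen only after the result was seen. The test on AHRR was set down before its value was seen.

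Further transcripts of airway epithelium, chosen after their values were seen, were found in all libraries. SERPINB3 of squamous and secretory cells averaged 462 CPM, the secreted protease inhibitor gene SLPI 313 CPM, BPIFB1 of airway mucus 229 CPM, S100A9 144 CPM, the ciliated cell regulator gene FOXJ1 108 CPM and the mucin gene MUC5AC 84.4 CPM. Basal cell KRT5 stood at 236 CPM, KRT8 at 231 CPM and EPCAM at 34.8 CPM. The median ratio between the highest and lowest donor was 1.11 for the epithelial list, against 1.28 over all tested genes. The lymphatic gene RELN varied between donors like PROX1, at 593, 4.66 and 244 CPM. The processed pseudogene EEF1A1P5, nearly identical to EEF1A1, stood at 6146 CPM and most of its reads are uncertain.

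TIPARP, CYP1A1 and CYP1B1 are textbook targets of the aryl hydrocarbon receptor, which suggests as a hypothesis that Hemin activated this receptor by 1.5 h. AHRR, a further target, stood at 0.11 on the log2 scale (unadjusted p = 0.285), which neither meets the hypothesis nor goes against it. With Hb3+ CYP1A1 stood at 0.66 (limma adjusted p = 0.127 by Benjamini-Hochberg).

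DUSP6, SPRY1 and SPRY4, which are induced by ERK and restrain it, fell with Hemin at 1.5 h. SPRY1 fell in replicates 1 and 2 and hardly in replicate 3 (-0.86, -1.29 and -0.06). Lower ERK output is a candidate explanation. Other immediate early genes went both ways, with IER3 (0.76) and FOSB higher and MYC lower, and their list was not called, so they do not bear it out as a set. The 12 ERK target and feedback genes that were not called had a mean log2 fold change of -0.043 (SE 0.087). Of these 6 of 12 were lower, and camera with an estimated correlation gave p = 0.464. The set left out the genes called in this same comparison, which pulls its mean towards 0. The test therefore does not decide, and the hypothesis stays open.

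ARRDC3 fell with both haemoglobins at both times and is related to TXNIP and ARRDC4, targets of the glucose-sensing factor MondoA. Lower MondoA activity with haemoglobin may be the reason, as a hypothesis. Of the 8 values of TXNIP and ARRDC4 over both haemoglobins and both times, 7 were below 0, and the exception was ARRDC4 with Hb3+ at 30 min (0.07, SE 0.11). At 30 min ARRDC3 already stood at -0.45 with Hb2+ and -0.60 with Hb3+. TXNIP stood at -0.13 and -0.06 there (SE 0.07) and ARRDC4 at -0.06 with Hb2+ (SE 0.11), not called. With Hemin at 1.5 h ARRDC3 rose by 0.49, while TXNIP and ARRDC4 both stood at -0.04. In these comparisons ARRDC3 changed where the other 2 were not found to. TXNIP was called with Hb3+ at 1.5 h (-0.33; limma adjusted p = 0.0303 by Benjamini-Hochberg), but the haemoglobins share their Ctrl libraries at each time, so the signs go together without an effect and the tally of 7 does not decide.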
